A study of Rattus norvegicus with 8 samples.

How the data were processed

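Small RNA from rat femur was sequenced in 8 libraries, 4 from hyperlipidemic and 4 from normal rats. Per the labels, male Wistar rats had been given a high-fat or a normal diet for 8 weeks, titanium implants were placed in the shafts of both femurs, and bone within 1 mm of the implant was collected 10 days later, when the rats were 12 to 13 weeks old. Muscle was removed before the bone was powdered in liquid nitrogen. Libraries were made with a small RNA kit that ligates adapters to both RNA ends, bands of 140 to 160 bp were cut from a gel, and 50-bp single-end reads were taken, per the labels' protocols. Adapter ligation and gel selection favour some miRNAs over others, so levels are best compared between libraries within a miRNA.

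The submitters' processing notes name bcl2fastq 1.8.4 and the build Rnor_6.0. The aligner, the miRNA reference, the program that predicted new hairpins and the counting rule are not given in the sources used here. The authors deposited 1 table of 974 miRNAs, of which 604 carry the rno- prefix of catalogued rat miRNAs and 370 are predictions named with novmiR and a chromosome. The authors gave the per-library values the name FPKM, but the deposited signal is in reads per 1000000 (RPM), scaled separately in the rno- and the predicted class. In each library the predicted class summed to about 1000000, and the rno- class to between 854151 and 909193. Within a class and library every low value was a whole multiple of 1 step, which is the worth of 1 read, and no length entered it. The share of values up to 20 reads that came out whole within 0.1 read was 100% in each class and library. Whole reads were recovered from these steps. Because each class has a step of its own, count models were not used as the main test, and 1 predicted read was worth 8.60 RPM against 0.475 for an rno- read (medians over the 8 libraries). A predicted and an rno- miRNA at the same value therefore rest on very different numbers of reads. The scaling by class also means that values cannot be compared between classes.

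The authors also deposited a fold (a ratio of hyperlipidemic over normal), its log2, a p-value, an adjusted p-value and a call in words, per the file headers. Their test is not given in the sources used here, and their fold is not the plain ratio of the deposited group means. Their adjusted p-values equal a Benjamini-Hochberg adjustment over all rows. The authors' calls follow the size of the log2 fold alone, with a threshold at 1. These values are cited as those of the authors' deposited table.

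Before the data were examined, the tests, 24 lists of miRNAs, the rule for naming miRNAs and most alternatives were fixed. Groups and replicate numbers came from the labels. The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), two-sided, on log2(value + 0.475), where the pseudocount 0.475 is the median over libraries of the smallest value above 0. Fitted folds are given on this scale. It is about 1 rno- read, which shrinks the folds of rno- miRNAs with few reads, but far below 1 predicted read, so the fold of a predicted miRNA with few reads against 0 comes out large and depends on the pseudocount. A miRNA was tested if it was above 0 in at least 4 libraries and its mean was at least 5 pseudocounts (2.375 RPM), which left 696 miRNAs, 396 rno- and 300 predicted. The threshold was a Benjamini-Hochberg adjusted p under 0.05. Lists were tested with camera in limma, with a preset correlation of 0.01 between members, and beside it with an estimated correlation and with fry. Members were matched by name with copy number and arm, so that both arms of a hairpin count. The lists cover miRNAs described as promoting or inhibiting osteoblasts and osteoclasts, lipid and cholesterol, adipogenesis and inflammation miRNAs, markers of 11 cell types, 5 seed or sequence families or clusters and the Dlk1-Dio3 cluster. The Dlk1-Dio3 list was drawn up with miR-653 in it by mistake: the reference table of the assembly GRCr8 places Mir653 elsewhere. Shares of the summed signal, of both classes as fixed beforehand and of the rno- class alone, were compared by exact permutation tests, two-sided, whose smallest possible p for 4 against 4 libraries is 0.0286, too large for a few separated measures to pass after adjustment.

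The rule for naming took the miRNAs past the threshold (up to 10 each way), those with the smallest unadjusted p up to 20 in all, the 10 most abundant, up to 4 members of each list (those past the threshold, then the highest means), and the 5 largest folds in the authors' deposited table. It yielded 102 miRNAs, of which the text names a part, picked after their values were seen. MiRNAs named outside it were chosen after their values were seen, and this is said where they stand. Hairpin names of 595 of the 604 rno- miRNAs were found in the GRCr8 reference table, which was used for names and neighbours alone, since its build differs from that of the authors.

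The reads behind the rno- scale ranged from 990804 to 4809893 per library and those behind the predicted scale from 60075 to 144051. A count of 0 in the shallowest library allows up to 3 reads, which is 3.03 RPM of the rno- class or 49.9 of the predicted class. Floors and intervals cover counting error alone, since PCR copies are not independent molecules. The labels say that each rat carried implants in both femurs and do not say which library came from which rat, so that p-values measure the spread between samples, of which some may share an animal.

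Alternatives fixed beforehand were other pseudocounts, filters and normalizations, no variance trend, a replicate block, an exact permutation test per miRNA, another threshold and each library left out in turn. Chosen after seeing the data were a pseudocount of 1 read per class, tests within each class, limma voom on the recovered reads, thinning of reads to equal depth (20 draws), scaling within each class, rescaling of rno- values without the erythroid list, lists without shared members or without miR-653, shares of the rno- class or of recovered reads, and leaving out 2 pairs of libraries that stood apart. The test was tried on simulated reads with the depths of the hyperlipidemic against normal comparison, with 718 miRNAs tested. Of the rno- miRNAs changed 2-fold, 21.6% were called, of those changed 4-fold 89.2% and of those changed 8-fold 100%. For predicted miRNAs these shares were 34.5%, 51.9% and 96.3%, and 5 unchanged predicted miRNAs (2.11%) were called against 0 unchanged rno- miRNAs. All changes stood in the same simulated draw, with 37, 37 and 38 rno- and 29, 27 and 27 predicted miRNAs changed 2-fold, 4-fold and 8-fold. So many true changes loosen the adjusted threshold. Where few miRNAs change, the shares called may be lower, so they do not give the power of the real comparison.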

Results

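The miRNAs of bone around titanium implants were profiled in 4 hyperlipidemic and 4 normal rat libraries, 10 days after implantation. Hyperlipidemia had been induced by a high-fat diet. The comparison asks how the miRNA content of bone at an implant differs between the 2 diets. The most abundant catalogued miRNAs were those of blood cells: miR-144-3p and miR-451-5p, which are red-cell miRNAs, and miR-142-5p, which is found across leukocytes. Of the 10 highest values 7 belong to predicted miRNAs, led by rno_novmiR_chr5_11378-5p (log2 fold -0.22, SE 0.40, adjusted p = 0.767 by limma), but only because that class is scaled by itself: the 10 miRNAs with the most recovered reads are all rno- miRNAs. Ranked by reads, a choice made after seeing the data, the first 10 held 55.1% ± 5.07 (SD, n = 4) of the reads in hyperlipidemic and 42.3% ± 9.47 (SD, n = 4) in normal libraries, which did not pass (exact permutation test, two-sided p = 0.0857). The measure fixed beforehand, the 10 highest values over the sum of both classes, mixes the 2 scales and is not a share of the reads; it gave 45.5% ± 5.04 and 36.2% ± 4.26 (SD, n = 4 each; exact permutation p = 0.0857).

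More reads stood behind the rno- values of the hyperlipidemic libraries than behind those of the normal ones. The rno- scale of the hyperlipidemic libraries rested on 4809893, 3150882, 2643501 and 3338297 reads and that of the normal libraries on 1748974, 1395992, 990804 and 1558475, so that every hyperlipidemic library had more than any normal one (two-sided exact permutation p = 0.0286, adjusted over 6 measures 0.0571, where 4 of the 6 would have to be fully separated for any to pass). The reads behind the predicted scale overlapped (115473 to 144051 against 60075 to 135400, exact permutation p = 0.114). Reads outside the 2 scales are not known, so deeper sequencing and a larger share of rno- miRNA in the reads are not told apart. The predicted class held 3.76% ± 1.10 (SD, n = 4) of the reads behind both scales in hyperlipidemic and 6.51% ± 1.02 (SD, n = 4) in normal libraries, again without overlap (exact permutation p = 0.0286, adjusted 0.0571). Predicted miRNAs listed at 0 numbered 65 ± 6.98 (SD, n = 4) and 100.5 ± 16.9 (SD, n = 4).

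**Figure D1:**
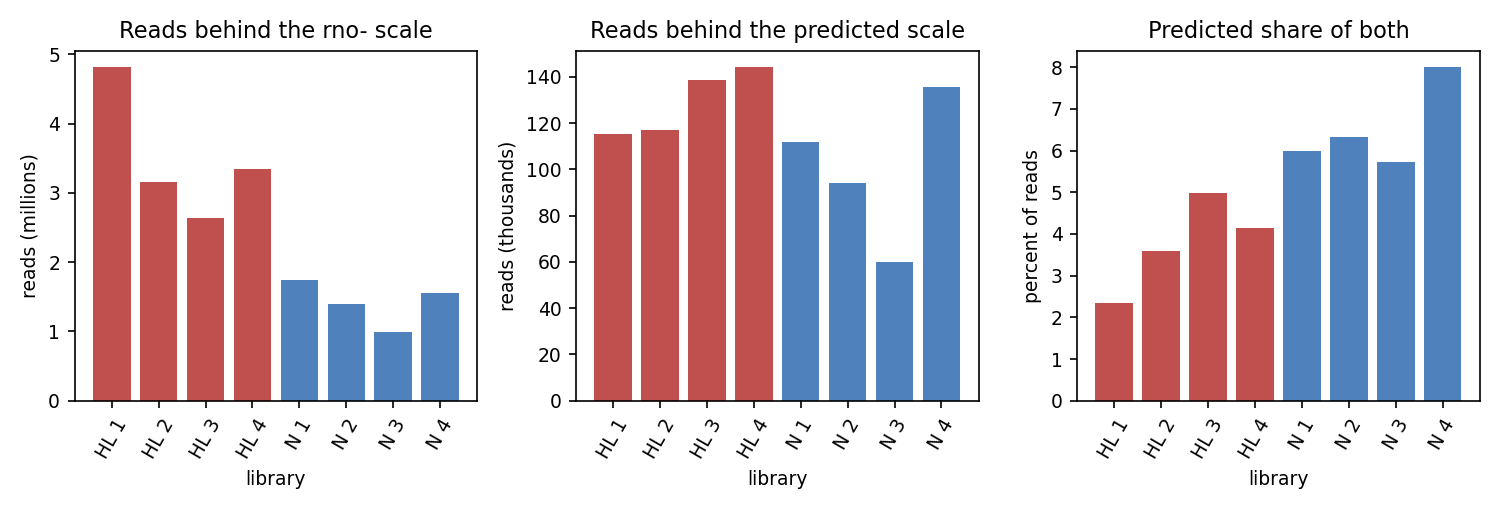
Bars show, for each hyperlipidemic (HL, red) and normal (N, blue) library, the reads behind the rno- scale, those behind the predicted scale, and the predicted share of both in percent. The rno- bars of the hyperlipidemic libraries run from 2643501 to 4809893 reads and those of the normal libraries from 990804 to 1748974, while the predicted share is lower in every hyperlipidemic library.

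The libraries were alike in the ranking of rno- miRNAs, and neither of the first 2 principal components separated the diets. Spearman's rho across miRNAs, which are not independent replicates, was 0.92 to 0.98 between libraries, with a median of 0.958 within and 0.956 between groups. The first principal component held 40.0% of the variance and set normal replicates 3 and 4 (scores 10.5 and 17.9) apart from the rest, with normal replicate 1 (-4.14) among the hyperlipidemic libraries (-9.26 to -3.34). The second held 28.1% and set hyperlipidemic replicate 3 (-12.6) and normal replicate 2 (-11.5) apart. Normal replicates 3 and 4 had less of the rno- signal in the erythroid list (9.04% and 7.86%) and in the myeloid list (9.40% and 6.13%) than normal replicates 1 and 2 (17.9% and above in both lists).

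No catalogued miRNA passed the threshold between hyperlipidemic and normal bone by limma, nor by voom on the recovered reads (lowest adjusted p = 0.0522). The closest were miR-205, an epithelial miRNA, at 48.8 ± 17.0 RPM (reads per 1000000 of its class) in hyperlipidemic against 14.2 ± 3.80 in normal libraries (SD, n = 4 each; log2 fold 1.72, SE 0.36, limma adjusted p = 0.0584), miR-653-5p at 37.3 ± 12.2 against 134 ± 60.2 (log2 fold -1.82, SE 0.41, limma adjusted p = 0.0729) and miR-449c-5p at 3.85 ± 2.08 against 20.8 ± 9.95 (log2 fold -2.31, SE 0.54, limma adjusted p = 0.0836). The 2 groups did not overlap in any of these 3. Lower values without overlap also came from miR-181a-1-3p (log2 fold -1.07, SE 0.25), miR-130b-5p (-1.23, SE 0.29) and miR-3068-3p (-1.41, SE 0.33), all with a limma adjusted p of 0.0836. Across the 696 miRNAs tested, 124 had an unadjusted p under 0.05 where chance gives 34.8, and among rno- miRNAs 12 of these were higher and 50 lower in hyperlipidemic bone. The groups did not overlap for 88 miRNAs (12.6%), against 2.86% by chance, and 42 of the 46 rno- miRNAs among them were lower in hyperlipidemic libraries.

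Direction depended on the scale. The median log2 fold over all miRNAs tested was -0.10, with -0.20 for rno- and 0.17 for predicted miRNAs, and median-of-ratios factors moved it to 0.11. With these factors the 124 nominal differences (48 higher, 76 lower) became 126 (80 higher, 46 lower). When the rno- miRNAs were tested alone, a choice made after seeing the data, miR-205, miR-653-5p and miR-449c-5p passed (adjusted p = 0.0417 for each by limma). With rno- values rescaled to their sum without the erythroid list, chosen likewise, the rno- median was 0.00 and miR-205 passed (adjusted p = 0.0392).

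**Figure D2:**
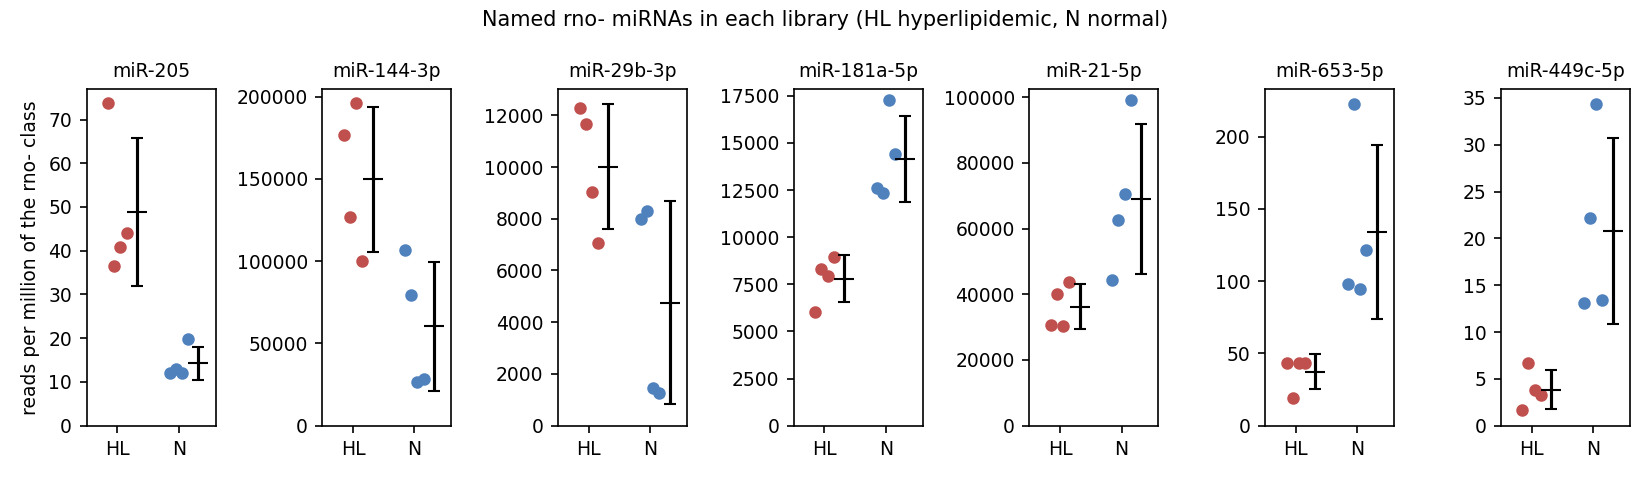
Points are RPM of the rno- class in each library for 7 named miRNAs (HL hyperlipidemic, red; N normal, blue), with the mean and SD of 4 libraries beside them; each panel has its own linear axis from 0. The groups do not overlap for miR-205, miR-181a-5p, miR-21-5p, miR-653-5p and miR-449c-5p, while normal libraries of miR-29b-3p fall in pairs.

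The 5 miRNAs that passed were all predicted and all higher in hyperlipidemic libraries, on very few reads. They were rno_novmiR_chr10_21410-3p with 12 reads over the 4 hyperlipidemic libraries, rno_novmiR_chr18_29593-5p with 9, and rno_novmiR_chr2_4009-5p, rno_novmiR_chr5_11780-5p and rno_novmiR_chr17_28625-5p with 6 each. All were listed at 0 in every normal library, with 514991 reads behind the class in hyperlipidemic and 401318 in normal libraries. Against a floor of 3 reads over the normal group they stood 3.12-fold, 2.34-fold and, for the last 3, 1.56-fold higher. These ratios take the hyperlipidemic reads as observed, without their counting error, so they are not lower limits. Limma's adjusted p was 0.00943 for 4 of them and 0.0137 for rno_novmiR_chr17_28625-5p. These values may be too small, since the test called too often in simulated comparisons of unchanged groups (below). With a pseudocount of 1 read per class none passed, and none passed without any 1 of hyperlipidemic replicates 1, 2 and 3, while 12 passed without normal replicate 1.

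Close behind were predicted miRNAs with 1 read in the normal group. The rows of rno_novmiR_chr7_15575-5p, rno_novmiR_chr16_27647-5p and rno_novmiR_chr7_15577-5p held identical values, with 18 reads in hyperlipidemic libraries (limma adjusted p = 0.0575), and rno_novmiR_chr6_13820-3p had 16 (limma adjusted p = 0.0584). In all, 81 predicted miRNAs shared all their values with another, and the 370 predicted names stood for 319 distinct profiles. Predicted miRNAs with lower values and more reads were rno_novmiR_chr6_12739-5p at 523 ± 132 against 1480 ± 494 RPM (SD, n = 4 each; log2 fold -1.48, SE 0.31, limma adjusted p = 0.0584) and rno_novmiR_chr4_10485-5p at 1763 ± 110 against 2961 ± 144 (log2 fold -0.75, SE 0.18, limma adjusted p = 0.0836).

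**Figure D3:**
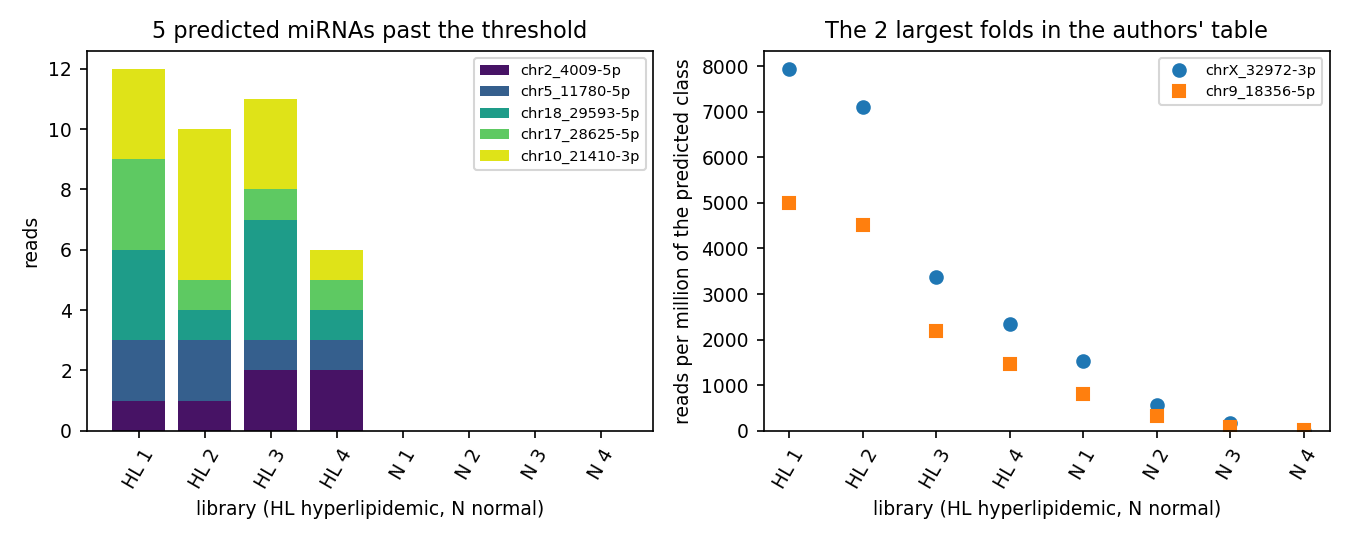
Left, stacked bars give the reads of the 5 predicted miRNAs past the threshold in each library (HL hyperlipidemic, N normal): the normal libraries hold 0. Right, points give the RPM of rno_novmiR_chrX_32972-3p (circles) and rno_novmiR_chr9_18356-5p (squares), whose values run from 7941 and 4997 in hyperlipidemic replicate 1 to 0 and 7.39 in normal replicate 4.

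The authors' deposited table calls 141 miRNAs up, 62 down and 771 unchanged. Of the 203 called there, 73 have an unadjusted p under 0.05 and 2 an adjusted p under 0.05 in the authors' deposited table, and 30 of those called up are at 0 in every normal library. The largest fold in the authors' deposited table is that of rno_novmiR_chrX_32972-3p (71.6-fold, adjusted p = 0.361), followed by rno_novmiR_chr9_18356-5p (33.3-fold, adjusted p = 0.292). These 2 had 2552 and 1617 reads in hyperlipidemic and 235 and 127 in normal libraries. In the limma test their log2 folds were 5.65 (SE 2.15, adjusted p = 0.233) and 4.66 (SE 1.24, adjusted p = 0.108), and without normal replicate 4, at 0 and 7.39 RPM, they fell to 3.12 and 3.37. All 5 miRNAs that passed here are called up in the authors' deposited table.

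Of the 24 lists, 3 passed by camera at the preset correlation between members and none with an estimated one, and 13 of the 35 ways to split the 8 libraries called at least as many. At the preset correlation inflammation and lymphoid miRNAs were lower and the Dlk1-Dio3 cluster was higher in hyperlipidemic libraries. Inflammation miRNAs had 29 of 33 tested members below 0 with a median log2 fold of -0.53 (camera adjusted p = 0.0036, and adjusted p = 0.785 with an estimated correlation). No member passed over all miRNAs tested, and 2 were lower when adjusted over the list alone, miR-181a-5p and miR-181a-1-3p. Abundant members were miR-21-5p, which is induced in injured and inflamed tissue, at 36230 ± 6760 against 69100 ± 22806 RPM (SD, n = 4 each; log2 fold -0.89, SE 0.28), and miR-146a-5p, which NF-kB induces, at 3641 ± 456 against 5896 ± 1378 (log2 fold -0.68, SE 0.23). The myeloid miRNA miR-223-3p, also in the list, lay the other way (log2 fold 0.38, SE 0.36). With median-of-ratios factors the list's median was -0.31, against -0.00 over rno- miRNAs and 0.11 over both classes. Camera set the list against both classes, whose main-scale medians were -0.20 (rno-) and 0.17 (predicted), which favours a lower call for rno- lists. With rno- miRNAs alone as the background the list still passed. Values are relative within the class, and the mean erythroid share was larger in hyperlipidemic libraries, with overlap between the groups and without passing (below). With rno- values rescaled without that list the median was also -0.31 (camera adjusted p = 0.0384).

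Lymphoid miRNAs had 10 of 13 tested members below 0 with a median log2 fold of -0.78 (camera adjusted p = 0.0264, and adjusted p = 0.785 with an estimated correlation). None passed over all, and the same 2 arms of miR-181a were lower when adjusted over the list alone. MiR-181a-5p stood at 7800 ± 1258 against 14165 ± 2274 RPM (SD, n = 4 each; log2 fold -0.86, SE 0.21, limma adjusted p = 0.0924) and miR-181b-5p at a log2 fold of -0.59 (SE 0.33). The lymphocyte miRNAs miR-150-5p (log2 fold 0.12, SE 0.21) and miR-342-3p (0.12, SE 0.30) did not share this direction. The list has 6 tested members in common with inflammation. Neither list passed without them, a choice made after seeing the data. The 27 other inflammation miRNAs had 23 below 0 (median -0.49, camera adjusted p = 0.0513). The 7 other lymphoid miRNAs went both ways, with 4 below 0 (median -0.74, camera adjusted p = 0.424). The lymphoid list did not pass without hyperlipidemic replicate 4 (median -0.81, adjusted p = 0.0527) or without normal replicate 2 (median -0.92, adjusted p = 0.144), though its median was no smaller there. With rno- values rescaled without the erythroid list it was smaller and the list did not pass (median -0.57, adjusted p = 0.0618).

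Members of the imprinted Dlk1-Dio3 cluster, high in fetal and mesenchymal tissue, had 33 of 43 log2 folds above 0 with a median of 0.42 (camera adjusted p = 0.0457, and adjusted p = 0.821 with an estimated correlation). No member passed over all or when adjusted over the list alone. Examples were miR-136-5p (log2 fold 1.87, SE 0.89) and miR-127-3p (0.09, SE 0.56). MiR-653-5p, listed here by mistake, was the lowest member, and without miR-653 33 of 41 were above 0 (camera adjusted p = 0.0176 at the preset correlation). That shorter list was not tested with an estimated correlation. The call of the full list was lost under most alternative settings. Among them were quantile normalization (median 0.17, adjusted p = 0.548) and leaving out normal replicate 2 (median 0.03, adjusted p = 0.439).

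**Figure D4:**
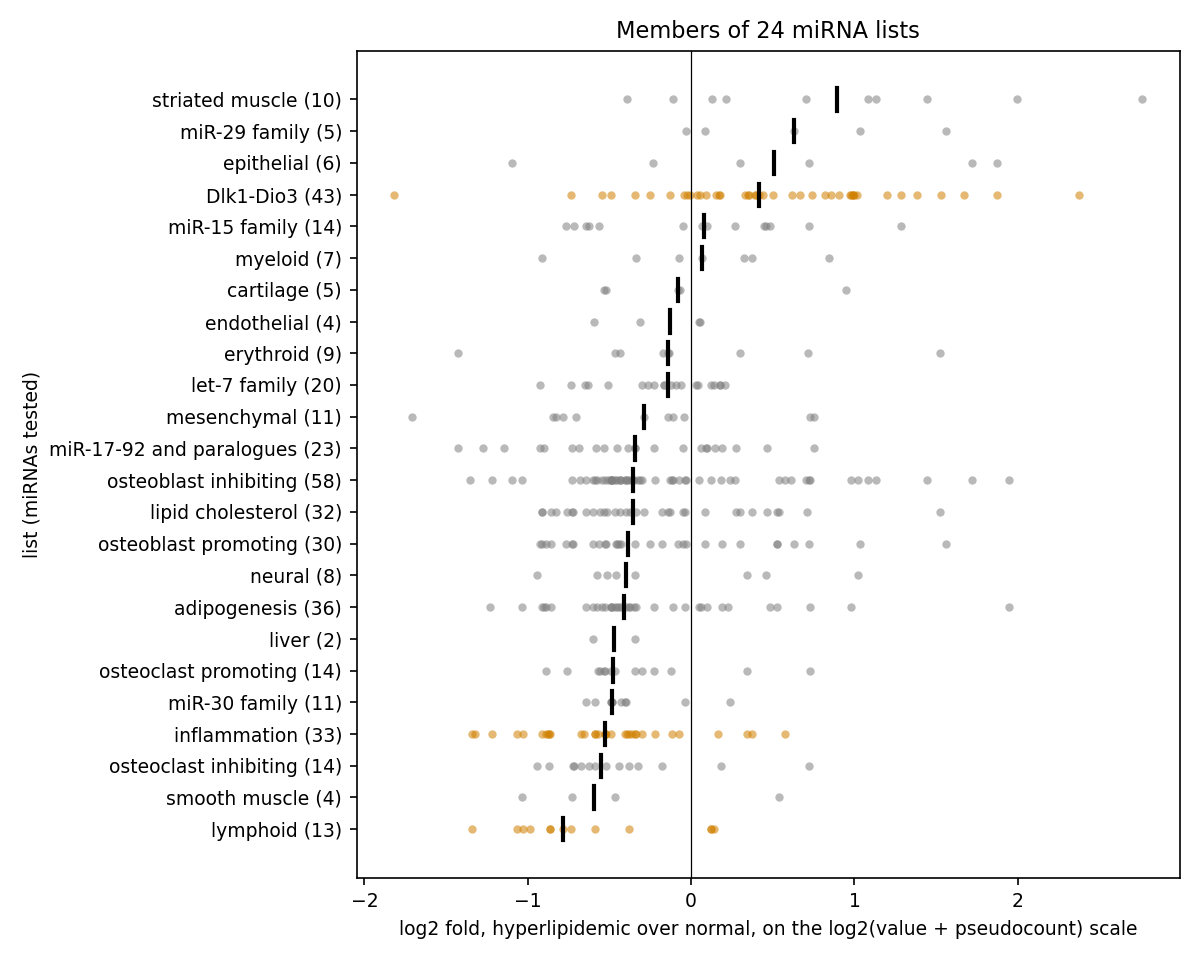
Each point is the fitted log2 fold of a tested member of a list, hyperlipidemic over normal, and black bars are list medians; the number tested stands beside each name, and orange marks the 3 lists with a camera adjusted p under 0.05 at the preset correlation. Medians run from -0.78 (lymphoid) to 0.89 (striated muscle).

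Lists tied to bone cells did not pass. Osteoblast-promoting miRNAs had a median log2 fold of -0.39 (camera adjusted p = 0.351) and osteoblast-inhibiting ones of -0.35 (0.440), and osteoclast-promoting and osteoclast-inhibiting miRNAs had medians of -0.48 (0.278) and -0.55 (0.148). With median-of-ratios factors the 4 medians were -0.17, -0.14, -0.27 and -0.34, and the rno- median of -0.20 became -0.00. No member of these 4 lists passed over all or when adjusted over the list alone. Abundant members were miR-26a-5p (log2 fold -0.18, SE 0.24), miR-27a-3p (0.52, SE 0.31), miR-148a-3p (-0.76, SE 0.35) and miR-214-3p (0.72, SE 0.39). The miR-29 family, which targets collagen transcripts, had 4 of 5 tested members above 0 with a median of 0.63 (camera adjusted p = 0.148). MiR-29b-3p stood at a log2 fold of 1.56 (SE 0.65) and miR-29c-3p at 1.03 (SE 0.41), but miR-29a-3p at -0.03 (SE 0.20). Without normal replicates 3 and 4, a choice made after seeing the data, miR-29b-3p was at 0.26 and miR-29c-3p at 0.31.

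Neither lipid and cholesterol miRNAs (median log2 fold -0.36, camera adjusted p = 0.375) nor adipogenesis miRNAs (-0.41, 0.148) passed, and none of their members did over all or when adjusted over the list alone. The miR-30 family had 10 of 11 members below 0 (median -0.48, camera adjusted p = 0.148), with miR-30e-5p at -0.49 (SE 0.22) and miR-30b-5p at 0.24 (SE 0.27). The let-7 family (median -0.14, adjusted p = 0.410, with let-7f-5p at -0.63, SE 0.30, and let-7g-5p at -0.65, SE 0.31), the miR-15 family (0.08, 0.717, with miR-16-5p at 0.27, SE 0.30, and miR-15b-5p at 0.72, SE 0.35) and the miR-17-92 cluster with its paralogues (-0.35, 0.148, with miR-19b-3p at -0.05, SE 0.43) did not pass either. None of their members or those of the miR-29 and miR-30 families passed over all or when adjusted over the list alone.

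Markers of blood cells made up a large part of the rno- signal. Shares are given of the rno- class alone, a choice made after seeing the data, since the sum over both classes that was fixed beforehand mixes 2 scales and makes each share smaller. The erythroid list held 25.8% ± 5.98 of the rno- signal in hyperlipidemic and 13.8% ± 6.22 in normal libraries (SD, n = 4 each; exact permutation p = 0.0571, adjusted over 11 lists 0.210), and 12.2% ± 2.90 and 6.44% ± 2.96 of both classes summed (SD, n = 4 each; the same p-values). MiR-144-3p stood at 149865 ± 44141 against 60314 ± 39407 RPM (SD, n = 4 each; log2 fold 1.52, SE 0.48, limma adjusted p = 0.153), and without normal replicates 3 and 4 at a log2 fold of 0.65. MiR-451-5p was at a log2 fold of 0.71 (SE 0.40) and miR-486, another red-cell miRNA, at -0.14 (SE 0.39), and the list did not pass (median -0.14, camera direction up, adjusted p = 0.880). Adjusted over the list alone 1 erythroid miRNA was lower, miR-363-3p, named after its value was seen. The myeloid list held 17.9% ± 2.45 against 13.5% ± 6.77 of the rno- signal (SD, n = 4 each; exact permutation p = 0.343), with a median log2 fold of 0.07 (camera adjusted p = 0.843), and miR-142-5p at 0.84 (SE 0.39) and miR-142-3p at 0.32 (SE 0.45). The lymphoid list held 1.63% ± 0.190 against 2.51% ± 0.297 (SD, n = 4 each), lower in each hyperlipidemic library than in any normal one, with the smallest exact permutation p that 4 against 4 allow (0.0286, adjusted over the 11 lists 0.210). At least 7 of the 11 lists would have to be fully separated for any share to pass after adjustment, so that these adjusted values decide nothing.

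Markers of other tissues did not pass as lists. For the 7 lists beside striated muscle, the exact permutation p of the share ran from 0.0571 (epithelial) to 0.629 (cartilage). Striated muscle held 0.422% ± 0.354 against 0.270% ± 0.261 of the rno- signal (SD, n = 4 each; exact permutation p = 0.543) and varied within groups, with 0.0271% in hyperlipidemic replicate 3 and 0.866% in replicate 1. Its members miR-1b (log2 fold 0.21, SE 1.19) and miR-133a-3p (0.70, SE 1.16) were as variable, and its median was 0.89 (camera adjusted p = 0.148). Without hyperlipidemic replicate 3 the list passed at the preset correlation of 0.01 (adjusted p = 0.00433), but the estimated correlation of its members was 0.637, with which it had an adjusted p of 0.813 over all libraries. Epithelial miRNAs had a median log2 fold of 0.51 (camera adjusted p = 0.148), with miR-205 higher when adjusted over the list alone (1 of 6), miR-141-3p at 0.72 (SE 0.45) and miR-203a-3p at 0.30 (SE 0.32). Mesenchymal miRNAs had a median of -0.29 (adjusted p = 0.392), with miR-199a-5p at -0.85 (SE 0.34), miR-199a-3p at -0.14 (SE 0.33) and miR-99a-5p at -0.11 (SE 0.33). Adjusted over the list alone 1 was lower, miR-152-5p, named after its value was seen.

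The remaining marker lists had camera adjusted p-values of 0.392 (smooth muscle, median log2 fold -0.60, with miR-143-3p at -0.46, SE 0.43), 0.823 (endothelial, -0.13, with miR-126a-3p at -0.60, SE 0.29), 0.843 (cartilage, -0.08, with miR-140-3p at -0.07, SE 0.40), 0.880 (neural, -0.40, with miR-338-3p at 1.02, SE 0.58) and 0.424 (liver, -0.47). No member of the 5 lists passed over all or when adjusted over the list alone. With an estimated correlation no list of the 24 passed (lowest adjusted p = 0.785), and fry, which asks whether a list's members move one way, called the lymphoid list alone (adjusted p = 0.0092).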

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

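The tests of leukocyte and red-cell content, depth, pseudocount, one-sided rows, shared reads and normal replicates 3 and 4 were chosen after the results were seen; the counts over other splits of the libraries were planned before.

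Within a group of 4, a library was singled out where its gap to the nearest other exceeded Dixon's 95% limit as a share of the group's range. This met 12 of 148 groups of values, where chance would give about 7.4 (1 in 20) for continuous and independent values. These are neither: a group with 1 read in 1 library and 0 in the others meets the limit by construction, and identical rows count separately. The 59 miRNAs covered are those named in the text, cut down from all those of the naming rule after an earlier run had been seen. With all of them the limit was exceeded in 19 of 234 groups. Normal replicate 1 had 8.96 RPM, which is 1 read, for rno_novmiR_chr7_15575-5p, rno_novmiR_chr16_27647-5p, rno_novmiR_chr7_15577-5p and rno_novmiR_chr6_13820-3p, with 0 in the other normal libraries. Hyperlipidemic replicate 1 had 25.98 RPM of rno_novmiR_chr17_28625-5p against 6.94 to 8.55 in its group. Hyperlipidemic replicate 2 was lowest for rno_novmiR_chr4_10485-5p (1598 against 1805 to 1827 RPM) and miR-653-5p (19.0 against 43.2 to 43.5). Normal replicate 4 was highest for miR-205 (19.9 against 12.0 to 12.9) and normal replicate 1 for miR-29a-3p (9952 against 8966 to 9110). Hyperlipidemic replicate 4 was lowest for miR-142-5p (72644 against 91471 to 95236) and highest for the share of endothelial miRNAs in both classes summed (0.854% against 0.449% to 0.509%). Normal replicate 4 had the highest such share of liver miRNAs (0.0482% against 0.0191% to 0.0231%).

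The first pattern is the 5 predicted miRNAs called higher with 0 reads in every normal library. Other splits of the 8 libraries argue against chance as the whole source of that count: 1 of the 35 splits, the real one, gave 5 calls, and the highest of the others gave 2. The size of the pseudocount may have made the calls, since it lies below the worth of 1 predicted read: with 1 read per class as the pseudocount, 0 of the 5 stayed past the threshold, their log2 folds went from 4.51 to 5.45 (SE 0.61 to 0.70) down to 1.18 to 1.81 (SE 0.36 to 0.42), and adjusted p rose to between 0.0655 and 0.136 because the spread fell less than the fold. Counting error at a few reads is not excluded by these rows: 5 predicted miRNAs had reads in all hyperlipidemic and no normal library and 0 the opposite, and 5 rows are too few for that test to pass (exact binomial p = 0.0625). In 100 simulated comparisons of unchanged groups at these depths the main test made a median of 0 calls and at most 3. Any call was made in 43. Where nothing changes, an adjusted p threshold of 0.05 should give any call in only about that share of comparisons. The main test's adjusted p was therefore too small in these simulations. Up to 3 false calls in a comparison were at 0 in every normal library, the form of the 5 calls here. In 0 of the 100 comparisons did the main test make 5 or more calls. These simulations use 1 spread between libraries per class, estimated from miRNAs with more reads. They therefore do not settle counting error for rows with so few. The simulation with changed miRNAs called 5 unchanged predicted ones, but its many true changes loosen the adjusted threshold, so it is not comparable. Counting error stays open as an explanation. A difference due to diet stays open and was not tested apart from these.

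The second pattern is the lower inflammation and lymphoid lists. Normal replicates 3 and 4 as the whole cause are argued against by leaving them out, after which the inflammation list had a camera adjusted p of 0.0134. After thinning to equal reads per class its camera adjusted p was 0.00586. Thinning keeps each row's expected share of the class, so it bears only on zeros and the pseudocount at few reads. It cannot decide on a difference in content that goes with depth. A loss of leukocytes from the hyperlipidemic samples stays open. The mean log2 difference of miR-142-5p, miR-142-3p, miR-223-3p, miR-150-5p and miR-342-3p was 0.36 (SE 0.32), above the inflammation median of -0.53. Without normal replicates 3 and 4 it was -0.18 (SE 0.13) against a median of -0.36, too close to decide. The share of the lymphoid list was lower in every hyperlipidemic library (1.63% against 2.51% of the rno- signal on average), which restates the pattern and does not bear on this. The mean myeloid share was larger there, with overlap (17.9% against 13.5%). A larger share of red-cell miRNA would lower all other rno- miRNAs alike. The median difference of the lymphoid list lay at -0.48 (SE 0.11) from that of the other rno- miRNAs, and at -0.33 (SE 0.09) without normal replicates 3 and 4. An equal lowering would not give such a gap, but the list was chosen as low in these same libraries. The gap partly restates that choice, which its SE does not allow for. A larger red-cell share is therefore not settled as the whole cause. Part of the fall goes with that share: rescaled without the erythroid list, the lymphoid median went from -0.78 to -0.57 and its call was lost (camera adjusted p = 0.0618). For the inflammation list this cause stays open as well, at -0.35 (SE 0.10) but -0.31 (SE 0.20) without normal replicates 3 and 4. Rescaled the same way, this list went from -0.53 to -0.31 and still passed (camera adjusted p = 0.0384). Chance cannot be excluded for the number of lists called: 13 of the 35 splits gave at least the 3 of the real one, and the highest of the others gave 5. Members that move together between libraries whatever the diet may explain this, since with an estimated correlation the adjusted p was 0.785 for both lists. That correlation was 0.166 in the inflammation list (camera p = 0.127 before adjustment) and 0.044 in the lymphoid list (camera p = 0.0386). For the lymphoid list the adjusted value is thus no sign of strongly co-moving members. An effect of diet stays open beside this.

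The third pattern is the pair rno_novmiR_chrX_32972-3p and rno_novmiR_chr9_18356-5p. Both may count reads of one source, such as sequences that match both places: over the 7 libraries with at least 5 reads of each, the SD of their log2 ratio was 0.15, against 2.00 for the less variable of the 2, and the first stood at 1.70 times the second. Thinning cannot decide on depth here. It keeps each row's expected share of the class, and both rows rest on many reads in the hyperlipidemic libraries. Their mean log2 fold was 5.64 after it against 5.16 before. Normal replicate 4 carries much of the size: without it the folds were 3.12 and 3.37. Whether the source differs with diet or between single animals stays open. The groups did not overlap in either (lowest hyperlipidemic 2333 and 1465 RPM against highest normal 1532 and 806), and voom called the second (adjusted p = 0.0417), but the values spread widely within both groups and limma called neither.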

How the results depend on the processing

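The tests within classes, with a pseudocount of 1 read, with voom, after thinning, within-class scaling, rescaling without the erythroid list, without shared list members, shares by reads or of the rno- class and without 2 pairs of libraries were chosen after seeing the data; the estimated correlation was fixed before, beside the main test of lists.

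The 5 calls became 10 with a pseudocount of 1 and 12 (11 higher, 1 lower) with one 5 times larger, 8 with median-of-ratios factors over all or within each class, and 23 (14 higher, 9 lower) at an adjusted p under 0.1. Each of these counts includes rno_novmiR_chr7_15575-5p, rno_novmiR_chr16_27647-5p and rno_novmiR_chr7_15577-5p, which hold identical values, so that they are 8, 10, 6 and 21 distinct profiles. Rescaling without the erythroid list gave 6, with miR-205 added (adjusted p = 0.0392). They became 0 with the stricter filter, with a pseudocount of 1 read per class, with predicted miRNAs alone, without hyperlipidemic replicate 3 and normal replicate 2 together, and by the exact permutation test (lowest adjusted p = 0.226, with 88 miRNAs at its smallest p, 0.0286, where 398 would be needed for any to pass). The rno- miRNAs alone gave 3 (1 higher, 2 lower), voom 1 (rno_novmiR_chr9_18356-5p, adjusted p = 0.0417) and thinned reads 3 (median of 20 draws, 0 to 5). The voom call is not among the 5. By its median adjusted p over the thinned draws no miRNA passed (limma, lowest 0.127), so the calls differed between draws. Leaving out each library in turn gave 0 (each of hyperlipidemic replicates 1, 2 and 3) to 12 (normal replicate 1, 10 distinct profiles). The no-filter, quantile and no-trend settings gave 5 each, and leaving out normal replicates 3 and 4 gave 7. The stricter filter left the called miRNAs untested; other causes were not tested.

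The 3 lists became 1 with the stricter filter, 6 (4 up, 2 down) with rno- miRNAs as the background and by voom, and 0 with an estimated correlation. For lists voom was run on rno- miRNAs alone, so it shares that background. Each library left out gave 1 (hyperlipidemic replicate 4 or normal replicate 2) to 5 (hyperlipidemic replicate 3). The inflammation list passed in 24 of 25 settings run on all lists (adjusted p = 0.000916 to 0.0282 with 1 library left out) and not with an estimated correlation (0.785) or without the members it shares with the lymphoid list (0.0513). The lymphoid list passed in 18 (0.00725 to 0.144 with 1 left out), and not with the stricter filter (0.319), an estimated correlation (0.785) or without hyperlipidemic replicate 3 and normal replicate 2 (0.0975) or the shared members (0.424), nor when rescaled without the erythroid list (0.0618), which left 2 lists called, or with the block, below. The Dlk1-Dio3 list passed in 11 (0.00129 to 0.439 with 1 left out), and not with a pseudocount of 1 (0.0511) or 5 times larger (0.0582), no filter (0.112), the stricter filter (0.654), median-of-ratios factors (0.101), quantile normalization (0.548), an estimated correlation (0.821) or without that pair of libraries (0.103). The cause was not tested.

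Lists that had not passed did so in some settings. With rno- miRNAs as the background these were striated muscle, epithelial and miR-29 family (camera adjusted p = 0.0277, 0.0277 and 0.0285). The same lists passed by voom on that same background (0.0285 each). Striated muscle also passed without hyperlipidemic replicate 3 and normal replicate 2 (0.0400), and the miR-17-92 list without normal replicates 3 and 4 (0.0384). With 1 library left out, striated muscle ran from 0.00433 (hyperlipidemic replicate 3) to 0.400 and miR-17-92 from 0.0376 (the same library) to 0.413. All of these are at the preset correlation. With an estimated one over all libraries the camera adjusted p was 0.813 for striated muscle and 0.785 for the epithelial, miR-29 and miR-17-92 lists. Other lists changed their direction in camera without passing. These were erythroid with no filter (0.769), quantile normalization (0.947), the block (0.992) and without hyperlipidemic replicate 3 and normal replicate 2 (0.922); myeloid with no filter (0.993) and without normal replicates 3 and 4 (0.531); neural and osteoblast-inhibiting with the rno- background (0.842 each) and voom (0.893 each); and cartilage with that background (0.963), voom (0.953) and within-class factors (0.994). Without normal replicates 3 and 4 this held for osteoblast-inhibiting (0.976), cartilage and the miR-15 family (0.805 each). It held for endothelial by voom (0.953) and for endothelial, cartilage and neural with rescaling without the erythroid list (0.990 each), and for neural after thinning (0.933) and with the stricter filter (0.654). With 1 library left out these lists ran from 0.685 to 0.964 (erythroid), 0.451 to 0.985 (myeloid), 0.547 to 0.925 (cartilage), 0.742 to 0.964 (neural) and 0.477 to 0.964 (miR-15 family). The cause was not tested.

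With the replicate block no miRNA passed (0 calls, lowest adjusted p = 0.0651), 1 list did, and the lymphoid and Dlk1-Dio3 lists had adjusted p-values of 0.0622 and 0.0940. The labels name no pairing, and the correlations of same-numbered deviations went both ways: 0.195, -0.082, -0.018 and 0.151 for replicates 1 to 4. The highest with another number were 0.027, 0.064, 0.081 and 0.057. Replicates 1 and 4 lay above these and replicates 2 and 3 below, so pairing by number is not settled.

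The difference in the share of the 10 most abundant miRNAs, 9.34 points, ranged from 7.80 to 11.5 points with 1 library left out, and passed at the latter (without hyperlipidemic replicate 4). Ranked and summed by recovered reads it was 12.8 points and did not pass (exact permutation p = 0.0857). With the rno- class as the denominator no cell type list passed in share (0 of 11), which decides nothing, since 7 of them would have to be fully separated for any to pass. No direction of a called result reversed. The plan fixed beforehand named edgeR for raw counts alone. The deposited values are scaled by class, so edgeR was not run, and voom was the only count-based model fitted to the recovered reads. The number of reads limits the predicted class most: 1 read there is worth 8.60 RPM.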

Other observations

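The X-linked cluster and the tests of arm ratios were chosen after the results were seen.

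A group of miRNA genes on the X chromosome, Mir450a1, Mir450b-1, Mir542, Mir351, Mir503 and Mir322, are neighbours in the GRCr8 reference table. Of their 12 arms tested, 11 lay below 0 in hyperlipidemic bone with a median log2 fold of -0.85, which describes a cluster picked because members were low and is no test of it. MiR-450b-5p stood at 1038 ± 385 against 2207 ± 546 RPM (SD, n = 4 each; log2 fold -1.12, SE 0.30), miR-450a-5p at a log2 fold of -1.16 (SE 0.33), miR-542-3p at -1.17 (SE 0.33) and miR-351-5p at -1.16 (SE 0.36). MiR-322-5p was at -0.05 (SE 0.35) and miR-542-5p at -0.00 (SE 0.41). None passed over all miRNAs (limma adjusted p = 0.112 for miR-450b-5p).

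The ratio of the 5p to the 3p arm was compared for 127 hairpins with both arms tested. None passed (limma, lowest adjusted p = 0.189), and 29 had an unadjusted p under 0.05, where chance gives about 1 in 20. Of the 696 single miRNAs tested 124 had one, so an excess is not particular to arm ratios. The ratio of miR-15b was higher by 1.29 on the log2 scale (SE 0.37) in hyperlipidemic bone. That of miR-132, whose less abundant arm stood at only 7.66 RPM, changed by -1.49 (SE 0.44).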
